A study of Caulobacter vibrioides and Caulobacter vibrioides CB15 with 4 samples.

How the data were processed

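Total RNA from synchronised swarmer cells of Caulobacter was compared on 4 two-colour Agilent arrays, 2 for strain ET166 and 2 for strain ET163, each carrying RNA of the wild-type strain CB15N (WT) in the other channel. Per the labels, swarmer cells were isolated on Percoll, brought to an OD600 of 0.4 in M2G minimal medium, grown for 15 min at 30 °C, and frozen, and 15 µg of total RNA was primed with random hexamers at 65 °C and labelled during reverse transcription. The strain's cDNA carried Cy5 and the WT cDNA Cy3 on all 4 arrays, so there was no dye swap. The design names 2 biological replicates of each strain and 3 of WT, so at least 1 WT RNA served more than 1 array. Which arrays shared it is not given in the sources used here.

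Per the file headers, the arrays were read with Agilent Feature Extraction 10.5.1.1, which gave for each spot the median intensity and the local background intensity of both channels. The same deposited files hold processed intensities, which Feature Extraction had background-subtracted and scaled linearly between the dyes, and a log10 ratio of red over green taken from them. The authors also deposited a table of log2 ratios per probe, made from the same arrays. The submitters' processing notes name limma with no version or setting. Set against the ratios computed here, the authors' log2 ratios had the same direction, correlations across probes of 0.997 to 1.00 and slopes of 0.997 to 1.00, and their array medians were 0.00015, -0.0090, 0.0065 and -0.013. Their scale, centring and direction were thereby settled from the values, and their exact steps stay unknown.

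Signals were taken from the scanner files. Spot means, which had been planned, are not among their columns, so the median intensities were used. Background was corrected with normexp at an offset of 50, ratios were normalised by loess within each array with control spots at a weight of 0, and control spots and spots with an outlier flag were left out, while saturated spots were kept. Probes had to be well above background in at least 1 channel on 2 arrays. That filter removed no probe of the class tested. All values are log2(strain/WT). The calculations used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

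Probe names carry a locus number, a middle number and a position, in places with a mark for the reverse orientation. The class without any mark, called forward here, holds 39206 probes of 3731 loci, 8 to 11 per locus with a median of 11. A locus value is the mean of its forward probes. The class marked reverse holds 4396 probes, and 3 smaller classes hold 249, 64 and 64 probes. The files do not state what the numbers stand for. Signal was lowest at positions 250 to 349 and rose from 350 on, and the windows of neighbouring loci can overlap. Whether a window begins upstream of the gene is not stated. The files do not pair locus numbers with gene names or products, and no annotation was used here, so loci are given by their numbers. Gene names are not reported.

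Each locus was fitted with limma, with 1 coefficient per strain over all 4 arrays, which leaves 2 residual degrees of freedom, and the variances were moderated by eBayes with a prior of 9.08 degrees of freedom and a prior SD of 0.14. The tests were two-sided. Each SE given comes from this moderated variance, pooled over both strains, and not from the spread of a strain's 2 arrays alone. The comparisons were ET166 against WT, ET163 against WT, ET166 against ET163, and the mean of both strains against WT. A locus counted as past the threshold at a Benjamini-Hochberg adjusted p under 0.05 over the 3731 loci. WT has no array without a strain, so the spread between WT cultures enters only through arrays that carried different WT RNA, and is left out where the arrays of a strain shared one. The dye effect of a probe stays in every comparison with WT and cancels between the strains as far as it was the same on every array. With 2 arrays per strain, the number of arrays limits the precision, and the median standard error was 0.097 for a comparison with WT and 0.14 for the difference between strains.

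The comparisons, the alternatives and the gene lists were fixed before the data were examined. The loci to be named were the 12 largest rises and the 12 largest falls per comparison among loci past the threshold whose arrays went the same way. Because no names are paired with the locus numbers, at most 2 rises and 2 falls per comparison are printed. Of 26 gene lists, 9 held locus numbers, 33 in all and all of them measured. These were written from general knowledge of the CB15 numbering and were not checked against an annotation. The 7 lists with at least 3 members were tested with camera, at its preset correlation and with an estimated one. They cover chromosome segregation, cell cycle regulators, cell division, SOS response and DNA repair, heat shock and proteases, general and envelope stress, and the S-layer. Pili, with 2 members, and cell shape, with 1 member, were too short to test.

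Position was taken from the order of the locus numbers. The loci were cut into 20 windows, and the largest window median and the variance of the window medians were set against 10000 orders in which blocks of 10 neighbouring loci were shuffled. The Spearman correlation with the distance from the replication origin, taken as the start of the numbering, was set against all circular shifts. Simulated groups without any strain effect, 100 in all, gave the correlation between strains that arises without an effect.

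The scripts were tested on simulated data. For ET166 against WT over 3731 loci, 95 of 100 loci with a planted log2 change of 0.5 and 100 of 100 with a change of 1 were recovered, with 20 false calls among the unchanged loci and mean fitted sizes of 0.43 and 0.88, so that fitted changes understate planted ones. For ET166 against ET163, 60 of 100 and 100 of 100 were recovered, with 14 false calls. For ET163 against WT, where nothing was planted, there were 4 calls. In the position tests, a raised stretch was found in 10 of 10 runs by both window statistics, and noise alone in 0 of 10. The test on distance from the origin found a planted gradient in 7 of 10 runs and passed in 4 of 10 runs that held only a raised stretch, so a raised stretch can make it pass.

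The alternatives changed the background correction, the signal, the normalisation within and between arrays, the dim-probe filter, the summary of probes, the source of the ratios, the test, a fold minimum, the replicate block, the slide and each array left out in turn. ET166 replicate 1 was alone on slide 2 and the other 3 arrays shared slide 1. ET166 replicate 2 was scanned alone on day 1 and the other arrays on day 2. Each block is therefore the same as leaving out that array. The scan day, the crossed pairing, the 2 parts of the probe window and the probes with a middle number of 1 were added as alternatives after seeing the data.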

Results

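Transcript levels in swarmer cells of 2 Caulobacter strains, ET166 and ET163, were measured against the wild-type strain CB15N on 4 two-colour arrays, 2 biological replicates per strain. Swarmer cells are the motile, non-replicating cell type that a Caulobacter division gives beside a stalked cell. The labels give neither the genotype of the strains nor the purpose of the comparison. The arrays read 3731 loci. The median intensity was 3349 to 5787 in the WT channel and 1767 to 7072 in the strain channel, which is 38.3 to 103 and 24.6 to 84.2 times the negative controls. ET166 replicate 2 had by far the brightest strain channel, 7072 against 1767 in ET166 replicate 1. ET166 replicate 1 had by far the most spots with an outlier flag, 1329 against 60 to 122 on the other arrays. The flagged spots were left out.

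The comparison of ET166 with WT asked which transcripts differ in that strain. CC1712 rose by 1.76 on the log2 scale, or 3.38-fold (SE 0.17, n = 2, limma adjusted p = 0.00031), and CC0681 rose by 1.63 (SE 0.17, limma adjusted p = 0.00035). These SEs are pooled over both strains, and the 2 ET166 arrays spread more widely, with an SD of 0.70 for CC1712 and 0.69 for CC0681. The order of the 2 loci was not firm. CC0681 lay higher on ET166 replicate 2, at 2.12 against 1.26, and from the probes numbered 350 or higher, at 1.97 against 1.48. Its own rise ran from 1.14 on ET166 replicate 1 to 2.74 with median centring. The largest falls were small beside these: CC2043 lay at -1.16 (SE 0.12, limma adjusted p = 0.00031) and CC1206 at -1.15 (SE 0.12, limma adjusted p = 0.00034). CC0681 lies in a stretch of 7 neighbouring loci, CC0678 to CC0684, all of which were higher than WT, with a median of 0.84 ± 0.20 (SD, n = 2). In all, 1465 loci passed the threshold, 752 higher and 713 lower, and 19 of them changed at least 2-fold, 11 higher and 8 lower. With median centring in place of loess, 222 did, 214 higher and 8 lower. Median centring leaves in the rise of the ratio with brightness that every array showed before normalisation. The split was 20 higher and 1 lower without ET166 replicate 1, and 26 higher and 22 lower without ET166 replicate 2. Most changes were small, with a median size of 0.41 among the loci past the threshold. Without ET166 replicate 1 the count fell to 120 loci, 108 of them higher. From the probes numbered 350 or higher, 1266 loci passed and 64.7% of them were higher, and from those numbered below 300, 1483 passed and 41.2% were higher, against 51.3% from all probes.

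ET163 against WT gave changes of the same order. CC1294 rose by 1.30 (SE 0.18, n = 2, limma adjusted p = 0.0013), or by 0.62 from the probes numbered 350 or higher (limma adjusted p = 0.034). CC1712, also high in ET166, rose by 1.22 (SE 0.17, limma adjusted p = 0.0013). CC2789 fell by 1.27 (SE 0.15) and CC3594 fell by 1.23 (SE 0.14), each with a limma adjusted p of 0.00072. A block of 22 neighbouring loci, CC1245 to CC1266, among the brightest on the arrays, held 21 loci that were higher than WT. Its median was 1.26 on ET163 replicate 2 but 0.35 on ET163 replicate 1, so most of its size came from 1 array. In all, 1477 loci passed the threshold, 682 higher and 795 lower, but with median centring 907 were higher and 768 lower of 1675. Of the 1477, 21 changed at least 2-fold, 7 higher and 14 lower. That balance turned round with median centring, with 158 higher and 19 lower of 177, and without ET163 replicate 1, with 28 higher and 6 lower. The count was 950 without ET163 replicate 1 and 790 without ET163 replicate 2. From the probes numbered 350 or higher, 1265 loci passed and 60.2% were higher, and from those numbered below 300, 1544 passed and 35.2% were higher, against 46.2% from all probes.

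Many of the loci that fell most were read by probes of a special kind. At 31 loci, over 50% of the forward probes had a middle number other than 1, and 25 of these were lower in ET166 and 26 in ET163, with medians of -0.73 and -0.81. Of the 12 largest falls, 10 were such loci in each strain, CC2043, CC1206 and CC2789 among them. Groups of these loci share probe positions and near-equal signals, as near-identical copies would, so their separate values are uncertain. With only the probes of middle number 1, the loci that fell at least 2-fold dropped from 8 to 1 in ET166 and from 14 to 5 in ET163, while CC2789 had no such probe. With these probes CC1206 lay at -0.17 in ET166 (limma adjusted p = 0.19) and at -0.22 for the mean of both strains (limma adjusted p = 0.023), and CC2043 at -0.56 and -0.48, still past the threshold.

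The 2 strains gave largely similar log ratios against WT. Their log ratios correlated across loci with a Pearson r of 0.833 and a Spearman rho of 0.860, where loci are not independent replicates. Pairs of arrays across strains gave r of 0.589 to 0.846, and the replicate pairs gave 0.797 in ET166 and 0.762 in ET163. Of the loci past the threshold, 485 were higher in both strains against 137 from independent lists of these sizes, 582 were lower in both against 152, and 7 went opposite ways. Groups were simulated without strain or dye effects, with 1 WT shared by 1 array of each strain and equal spread of WT and strain RNA. They gave r of 0.252, which these settings largely fix, and a covariance of 0.0036, against an observed covariance of 0.088. Which arrays shared a WT RNA is not known, so part of the excess may come from sharing other than that simulated. A dye response of single probes, which the simulation left out, may give part or all of it. For the mean of both strains, 2168 loci passed, 1053 higher and 1115 lower, with 5 higher and 12 lower at least 2-fold. With median centring both balances turned round, to 1255 higher and 1102 lower, and to 181 higher and 7 lower at least 2-fold. Median centring leaves in the rise of the ratio with brightness, while loess centres the ratios at each brightness. The balance under either setting therefore does not show a net direction. CC1712 stood at 1.49 (SE 0.12, n = 4, limma adjusted p = 3.2e-05) and CC3514 at 1.19 (SE 0.095, limma adjusted p = 2.4e-05), while CC2043 and CC1206 each lay at -1.16. From the probes numbered 350 or higher 62.0% of the calls were higher, and from those numbered below 300 40.2%, against 48.6% from all probes. The reverse probes, which are marked as the opposite orientation, gave calls about as often as the forward ones, but more of them lower. In ET166 39.8% of 3502 loci passed on reverse probes and 39.3% on forward probes, and in ET163 36.0% and 39.6%. The reverse calls were 506 higher and 888 lower in ET166, and 351 higher and 909 lower in ET163.

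**Figure D1:**
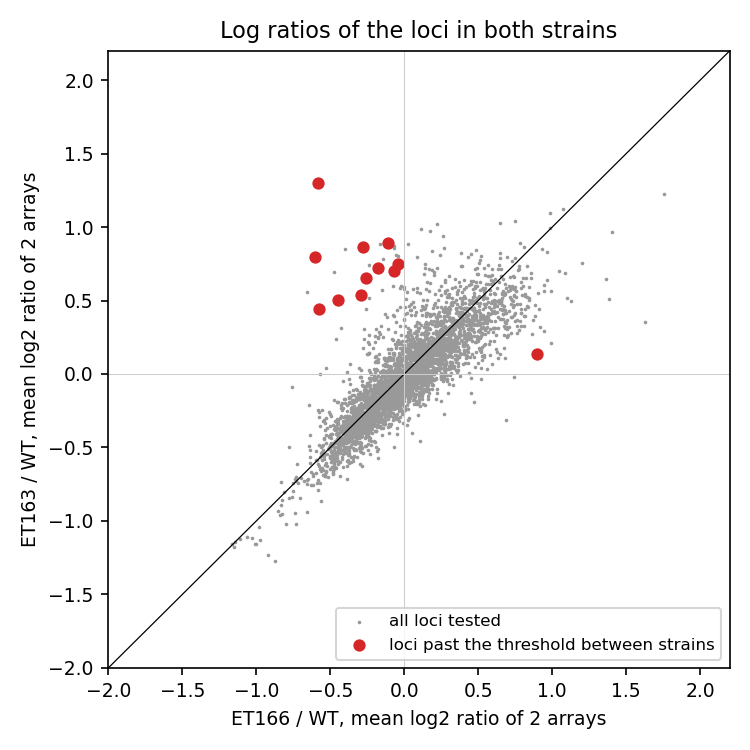
Mean log2 ratio to WT of each of the 3731 loci in ET166 (horizontal axis, 2 arrays) and ET163 (vertical axis, 2 arrays), with the line of equal change. The 12 loci past the threshold between the strains are in red, and 11 of them lie above the line, with ET163 means of 0.44 to 1.30.

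The direct comparison of ET166 with ET163 separated few loci. In it a probe's dye effect cancels only as far as it was the same on every array. At an unadjusted p under 0.05 in limma, 243 of 3731 passed, where a share of 0.05 would pass if no locus differed. Only 12 passed the threshold, 1 higher and 11 lower in ET166. All 11 were higher than WT in ET163 (means of 0.44 to 1.30), and their ET166 means lay between -0.60 and -0.04, with 5 of them called lower than WT. CC1304 differed most firmly, at -0.60 ± 0.14 (SD, n = 2) in ET166 and 0.80 ± 0.02 (SD, n = 2) in ET163, a difference of -1.40 (SE 0.14, limma adjusted p = 0.0018). CC1294 differed by -1.89 (SE 0.26, limma adjusted p = 0.016) over all its probes, but by -0.87 from the probes numbered 350 or higher (limma adjusted p = 0.58). Its neighbour CC1295 was also called, on 3 probes from 350 on that differed by -3.13, while its 6 earlier probes differed by 0.04. The 4 neighbouring loci CC2137 to CC2140 were all called and lay at -0.23 ± 0.18 (SD, n = 2) in ET166 and 0.63 ± 0.06 (SD, n = 2) in ET163. From the probes numbered 350 or higher these loci differed by -0.83, -0.53, -1.07 and -1.15, and none passed (limma adjusted p = 0.14 to 0.57). CC0683, at 0.90 ± 0.12 in ET166 and 0.14 ± 0.01 in ET163 (SD, n = 2), was the only locus called higher, by 0.76 (SE 0.13, limma adjusted p = 0.044). Its 7 probes below 350 differed by 1.04 and its 4 later ones by 0.27 (limma adjusted p = 0.96). The count depended on the array: it was 0 without ET166 replicate 2, with 138 at an unadjusted p under 0.05, 5 without ET166 replicate 1, 79 without ET163 replicate 1 and 38 without ET163 replicate 2. The first of these equals the scan day as a block and the second the slide as a block. The reverse probes gave 0 calls in limma and 101 at an unadjusted p under 0.05.

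**Figure D2:**
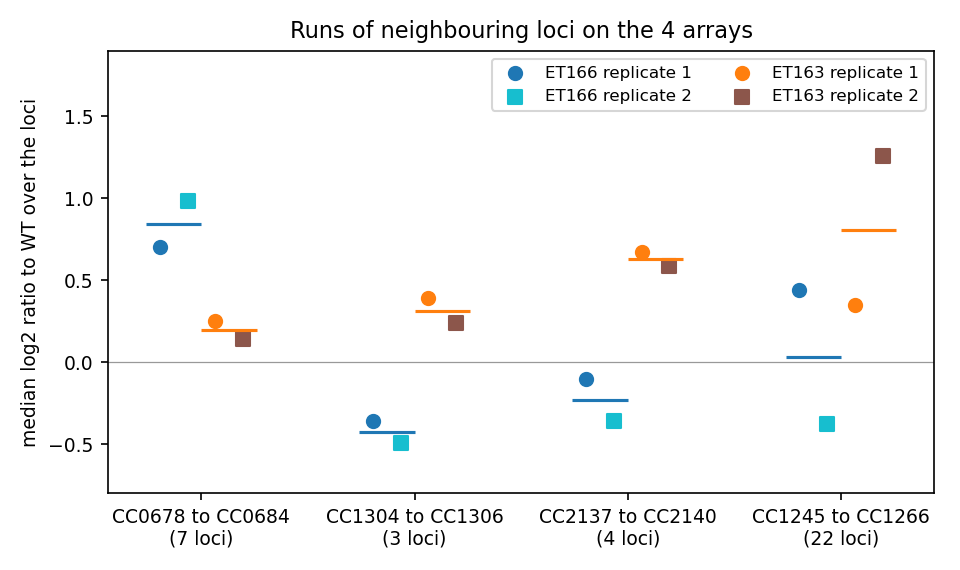
Median log2 ratio to WT over the loci of 4 runs of neighbouring loci, each point 1 array (blue and cyan ET166, orange and brown ET163) and each line the mean of a strain's 2 arrays. CC2137 to CC2140 lay at -0.10 and -0.36 on the ET166 arrays and at 0.67 and 0.59 on the ET163 arrays, while the arrays of CC1245 to CC1266 spread from -0.38 to 1.26.

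Gene lists showed few coordinated changes. Over all 3731 loci, 39.3% passed in ET166, 39.6% in ET163 and 58.1% for the mean of both strains. Counts of list members near these shares are no sign of a change in a list. The 3 S-layer loci, the paracrystalline coat of the cell and its export, were all higher in ET163, with a median of 0.57 (camera adjusted p = 0.031, and adjusted p = 0.68 with an estimated correlation), and 2 of 3 were higher in ET166 (median 0.58, camera adjusted p = 0.14). Adjusted over the list alone, the counts were likewise 3 and 2. These S-layer loci are the neighbours CC1007 to CC1009. Other lists hold neighbours too, such as CC3475 to CC3477 for stress, CC2540 to CC2542 for cell division, and CC2947 and CC2948 for pili. Neighbouring loci changed together and their windows can overlap, so such members may not count as separate observations. Of 4 loci for general and envelope stress, 2 were higher in each strain, and adjusted over the list alone 2 in ET166 and 4 in ET163 (camera adjusted p = 0.21 and 0.12). Among 9 cell cycle regulators, 2 were higher and 1 lower in ET166, and 3 higher and 1 lower in ET163, with the same counts adjusted over the list alone (camera adjusted p = 0.48 and 0.44). Of 3 loci for the SOS response and DNA repair, 1 was higher in ET166, and 2 were higher and 1 lower in ET163 (camera adjusted p = 0.55 and 0.44), unchanged when adjusted over the list alone. Of 4 for chromosome segregation, 1 was higher in each strain, also adjusted over the list alone (camera adjusted p = 0.70 and 0.44). For heat shock and proteases, 1 of 4 was higher in ET166 and 0 adjusted over the list alone, with 0 of 4 in ET163 either way (camera adjusted p = 0.48 and 0.44). Cell division had 0 of 3 past the threshold in both strains, also adjusted over the list alone, with medians of 0.25 and 0.24. The 2 pili loci stood at -0.19 and -0.24 in ET166, where neither passed, and were both higher in ET163, at 0.31 and 0.52. The 1 cell shape locus passed in neither strain. For the mean of both strains no list passed camera (smallest adjusted p = 0.079, for the S-layer), though single members passed: all 3 for the S-layer, all 4 for stress, 2 of 3 for cell division, 3 higher and 1 lower of 9 cell cycle regulators, 2 higher and 1 lower of 3 for SOS, 1 of 4 for segregation and 1 of 4 for heat shock. Adjusted over the list alone the cell cycle count was 2 higher and 1 lower. Between the strains no list passed camera (every adjusted p = 0.999) and 0 members passed over all loci, while adjusted over the list alone 1 of 9 cell cycle regulators and both pili loci were lower in ET166, the latter with limma adjusted p of 0.052 and 0.39 over all loci.

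Along the order of the locus numbers, the window from CC1883 to CC2072, with 186 loci, had a median of 0.25 in ET166 (permutation p = 0.0001, the smallest these permutations can give) and 0.18 in ET163 (permutation p = 0.0005), and it was above 0 on all 4 arrays, at 0.27, 0.19, 0.10 and 0.23. It held 77 loci higher and 9 lower in ET166, and 62 higher and 17 lower in ET163. Without ET163 replicate 2 another window led in ET163, CC2637 to CC2827 at -0.13 (permutation p = 0.041). The 3 adjoining windows from CC2637 to CC3202 lay below 0 on all 4 arrays, with medians of -0.10, -0.12 and -0.11 in ET166 and -0.16, -0.11 and -0.14 in ET163, and were not tested singly. Cut into 10 windows, the largest median was 0.12 in ET166 (permutation p = 0.0005) but a low one in ET163, at -0.13 (permutation p = 0.0005), and for the mean of both, at -0.11 (permutation p = 0.0038). For the mean of both strains the median of CC1883 to CC2072 was 0.22 (permutation p = 0.0001). The variance of the 20 window medians exceeded that of shuffled orders in all 4 comparisons (permutation p = 0.0001 each). Distance from the origin explained little: Spearman's rho was 0.0989 in ET166 (p = 0.023 by permutation over circular shifts, a test that a raised stretch alone can pass), 0.0947 in ET163 (permutation p = 0.44) and 0.101 for the mean of both (permutation p = 0.13). With median centring the ET166 value fell to 0.0237 (permutation p = 0.31). Between the strains the largest window median was 0.08, for CC0189 to CC0374 (permutation p = 0.052), and the rho with distance was 0.0265 (permutation p = 0.87).

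**Figure D3:**
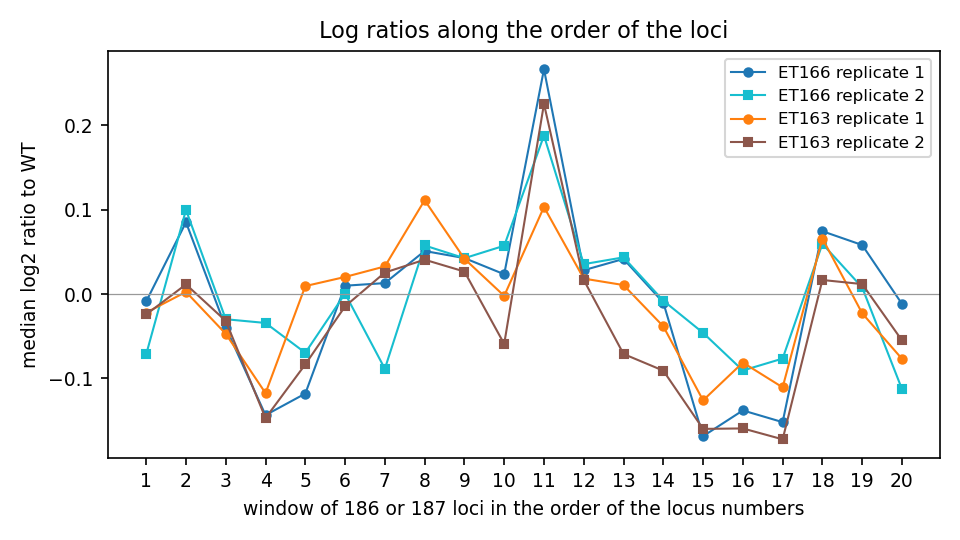
Median log2 ratio to WT on each of the 4 arrays in 20 windows of 186 or 187 loci, in the order of the locus numbers. Window 11 is the highest on ET166 replicates 1 and 2 and on ET163 replicate 2, at 0.27, 0.19 and 0.23, and lies at 0.10 on ET163 replicate 1.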

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

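The tests on shared WT RNA, dye response, overlapping windows and near-identical copies were chosen after the result was seen. The tests on slide or scan day and on probes with a middle number other than 1 at further loci were set before their results were seen.

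The 12 loci that separated ET166 from ET163 were singled out because the strains differed by a test of the difference itself. CC1304 differed by -1.40, CC1294 by -1.89 and CC0683 by 0.76 on the log2 scale. Neighbouring loci differed together. At an unadjusted p under 0.05 in limma there were 18 runs of 3 or more neighbouring loci with the same direction. In 1000 shuffled orders the median was 0 and the highest 3. The shuffles moved single loci, so anything that neighbours share, spread between cultures included, could give runs. Comparisons with WT also gave runs, 206 in ET166 and 196 in ET163, against at most 117 and 108 in shuffled orders. The run count therefore does not by itself show an effect of the strain. Between the strains, the probes numbered 350 or higher gave 5 runs against at most 2 in shuffled orders (permutation p = 0.001, the smallest these permutations can give). That met the bound first set against overlap of the probe windows as the whole cause. A check added after that left overlap open, as these probes do not exclude it: of 12 loci whose later probes differed from their own earlier ones by over 1, 7 had later probes within 0.5 of the earlier probes of a neighbour, against at most 4 with random loci as neighbours. Neighbours that change together could raise that count too, and no window was placed on a genome. At CC1294 the 6 probes below 300 gave -0.98 ± 0.85 (SD, n = 2) in ET166 and 1.74 ± 0.25 (SD, n = 2) in ET163, and the 3 probes of CC1295 from 350 on gave -1.64 ± 0.67 and 1.49 ± 0.26, while the 6 earlier probes of CC1295 gave -0.04 ± 0.16 and -0.08 ± 0.12. Slide or scan day stays open, since strain differences from separate pairs of arrays correlated at -0.026 across loci when paired by replicate number and at 0.28 when crossed. These differences may reflect the unknown genotypes, which the data do not test.

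The log ratios against WT that both strains share, with r of 0.833 across loci, raise the question of a common technical source. A single WT RNA on 1 array of each strain is argued against as the whole cause, since the lowest of the 4 correlations across strains was 0.589. A dye response of single probes cannot be told apart from a shared biological change: the strain was in Cy5 on every array and 0 arrays had swapped dyes. The reverse probes, which carried the same dyes, correlated across strains at 0.681 to 0.875, as a dye response could give. The forward probes correlated at 0.589 to 0.846. A change common to both strains, for example from how they were built, is untested and open too.

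The loci read mostly by probes with a middle number other than 1 lay below WT in both strains, at 25 of 31 in ET166 and 26 of 31 in ET163. Position-matched probes of those sharing at least 5 labels differed by a median of 0.35 in log2 intensity, against 1.65 between random probes, so a few signals are likely counted many times: 16 of the loci fall into 4 groups. Probes of this kind also read low elsewhere, with a median ratio of -0.41 over 551 probes at 343 further loci, below 0 on all 4 arrays, against 0.02 for the remaining probes. Both observations are consistent with a property of these probes. The 69 probes of middle number 1 at the loci in question also lay low, at -0.21 as a mean of the 4 arrays and below 0 on each, so a fall of the repeated sequences themselves stays open. None of this bears on the 11 loci lower in ET166 than in ET163, where 1 of 116 probes is of this kind.

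The pili loci were singled out because both passed between the strains when adjusted over the list alone, 2 of 2, at -0.22 ± 0.03 (SD, n = 2) in ET166 and 0.41 ± 0.08 (SD, n = 2) in ET163. They are the neighbours CC2947 and CC2948, so they may not count as separate observations. From the probes numbered 350 or higher they differed by -0.44 and -1.13, and neither passed over all loci (limma adjusted p = 0.89 and 0.13). The reverse probes of the class whose names carry the word ori went opposite ways, at 0.06 and 0.16 on the ET166 arrays and -0.15 and -0.03 on the ET163 arrays, a difference of 0.20 that was not tested. The forward probes of that class overlapped between the strains, at -0.06 and 0.13 against -0.17 and -0.06. Probe classes other than the forward probes of the main comparisons gave signals over the level of the negative controls: 33.9 times for the reverse probes, 41.3 times for the ori class, 38.9 times for that class in reverse and 49.2 times for the class whose names carry the word miss.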

How the results depend on the processing

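The parts of the probe window, the middle number, the scan day and the crossed pairing were chosen after seeing the data. Aquantile, no dim filter and, for the difference, array weights changed no count.

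The counts against WT stayed within 1.5 times of 1465, 1477 and 2168 under the other settings, except these. A minimum log2 ratio of 1 left 19 loci in ET166, 21 in ET163, 17 for the mean and 4 of 12 between strains, by construction. Leaving out 1 array in turn gave 120 to 1624 for ET166, 790 to 1386 for ET163, 1397 to 1982 for the mean and 0 to 79 between strains. With the slide as a block there were 120 in ET166, 1397 for the mean and 5 between strains. A strain left with 1 array is assumed to vary like the other. These fits have 1 residual degree of freedom, and their prior weight ran from 6.55 to 75.7 degrees of freedom. The fits without ET166 replicate 1 and without ET166 replicate 2 had the same prior of 6.55, so the prior does not separate their counts in ET166, 120 and 1036. For the fits without an ET163 array the prior and the array were not separated. Median centring, which leaves in the rise of the ratio with brightness, raised the number of loci changed at least 2-fold. They went from 19 to 222 in ET166 and from 21 to 177 in ET163. The probes numbered 350 or higher raised them to 70 and 50.

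Between strains, the count was 1 with no background correction, 1 with Agilent's processed signals and 2 with the median of probes. It was 4 with median centring, 19 with the authors' table and 2 from probes numbered 350 or higher. The first 3 settings had priors of 5.23, 6.25 and 6.41 degrees of freedom against 9.08. Their counts at an unadjusted p under 0.05 in limma were 240, 266 and 241, against 243. The probes numbered 350 or higher had a prior of 5.51 and 220 such loci. The authors' table had a prior of 11.7 and 261 such loci. Median centring had a prior of 12.4 but 138 such loci. The cause was not tested.

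With the replicate block, for which same-numbered arrays deviated at r of -0.30, 41 loci passed between strains, 1082 in ET166, 1150 in ET163 and 1855 for the mean, and 1 list for the mean. That fit has 1 residual degree of freedom and an infinite prior, so all loci share 1 variance. With 2 arrays per strain the crossed pairing has the same correlation with its sign turned, so nothing beyond that sign favours it. It gave 54 between strains, 1808 in ET166, 1762 in ET163 and 2380 for the mean.

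The correlation of the strains was 0.670 to 0.880 with 1 array left out, lowest without ET166 replicate 1, and 0.810 to 0.908 otherwise.

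List calls were few. Against 0 in ET166, 2 passed with scan day as a block and 0 to 2 with 1 array left out. Against 1 in ET163, 0 passed with processed signals, the slide as a block, scan day as a block, probes numbered 350 or higher, probes below 300 and an estimated correlation, 2 with the crossed block, and 0 to 3 with 1 array left out. Against 0 between strains, 2 passed with the slide as a block, 1 with scan day as a block and 0 to 2 with 1 array left out. Against 0 for the mean, 3 passed with scan day as a block and 0 to 3 with 1 array left out. The S-layer in ET163 had an adjusted p of 0.014 to 0.68. The cause was not tested.

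Cut into 20 windows, CC1883 to CC2072 led in ET166 in every setting run. Another window led in ET163 without ET163 replicate 2 (permutation p = 0.041), and in ET163 and the mean from probes below 300 (permutation p = 0.0063 and 0.029). With 10 windows, the largest was a low one in ET163 and the mean. Between strains the largest window median, 0.08 with a permutation p of 0.052, passed at 0.0798 with offset 0, 0.0730 with processed signals, 0.119 with median centring, 0.0610 with the median of probes, 0.0844 with the authors' table, 0.119 with the slide as a block, 0.0862 from probes numbered 350 or higher, 0.0894 below 300 and 0.0892 with scan day as a block, and ran from 0.0883 to 0.129 with 1 array left out (permutation p = 0.00020 to 0.18, and 3 of 4 passed). The leading window was not the same throughout, so these are not passes of CC0189 to CC0374 alone. Spearman's rho with distance in ET166 no longer passed at 0.0237 with median centring or 0.0669 from probes numbered 350 or higher. For the mean it passed at 0.118 with the slide as a block, 0.0637 from probes numbered 350 or higher and 0.0997 with the middle number 1, and ran from 0.0860 to 0.118 with 1 array left out. The cause was not tested.

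CC1712, CC0681, CC2043, CC1206, CC1294, CC3594, CC2789, CC0683, CC1304 and CC3514 kept their direction, in the comparisons they were named for, in the alternatives run. CC0683 lost its call in 10 of 23, CC1294 between strains in 6, CC1304 in 2 and CC1206 in ET166 in 1. Of the 23, Aquantile and no dim filter could not differ from the main setting. With 1 array left out CC1304 stayed at -1.50 to -1.30 and CC0683 at 0.68 to 0.84, so lost calls there do not show smaller changes. Dim filters tested little: over 99.98% of spots, reverse included, were well above background in both channels.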

Other observations

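The raised stretch CC1883 to CC2072 also stood out on the reverse probes. Over 179 loci their median was -0.00 as a mean of the 4 arrays, the highest of the 20 windows, the next being -0.05 for CC0189 to CC0374. The window medians of the reverse probes otherwise lay between -0.09 and -0.26, since reverse probes as a class lay at -0.15 in both strains.

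The ratio to WT shifted along the probe window. The median of the forward probes was -0.03 at positions 0 to 49 and 0.14 at positions 400 to 449, where the WT channel was also brighter, at 12.3 against 12.1 on the log2 scale. Before normalisation, the ratio rose with brightness on every array, from -1.92 at a mean log2 intensity of 9 to 10 to 0.57 at 15 to 16 on ET166 replicate 1, and from -0.46 to 0.93 on ET166 replicate 2.

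The block CC1245 to CC1266 showed the widest spread between replicates among the runs plotted. Its median was 0.44 and -0.38 on the ET166 arrays and 0.35 and 1.26 on the ET163 arrays, so replicates of a strain differed by more than the strains' means of 0.03 and 0.80. Its loci lay at the 99.1st percentile of brightness, and 0 spots of the named loci were saturated. No locus of the block passed between the strains.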
